A study of Homo sapiens with 2 samples.

How the data were processed

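Chromatin immunoprecipitation followed by sequencing was applied to MCF-7 cells, an established line from a human breast adenocarcinoma. Per the labels, 1 sample was precipitated with an in-house rabbit polyclonal antibody against H1.4K34ac, the linker histone variant H1.4 acetylated at lysine 34, and 1 sample was a control without antibody. Both come from formaldehyde-fixed cells whose nuclei were sonicated, with Illumina libraries, per the labels' protocols. Per the series' design text, 2 replicates of the H1.4K34ac precipitation, sequenced as separate runs, were turned into a single region list, so the spread between them cannot be seen in the list. Each group was therefore represented by 1 list, and every test below treats listed regions, not cultures, as its units. Such a p-value describes these lists and has no replicate check.

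Each file is a list of genomic regions with a start, an end, a number and a score. The authors deposited the score as a value per region that rises with significance. The regions carry MACS peak names in both files, and the track line of the control file names MACS run in Galaxy, per the file headers. The MACS version, its settings, the aligner and the library used as background for either list are not given in the sources used here. The genome build is hg18 per the submitters' processing notes. The lowest scores were 50.0 in the H1.4K34ac list and 50.09 in the control list. A value of 50 is what -10 times the log10 of a p-value of 1e-05 gives, but the scale is not stated. If the lists were called against different backgrounds, their scores are on different footings, so scores were used only to rank and describe regions within a list. Read counts and library depth are unknown here, so no depth-based interval was set on a region's own value. The control file's name describes its regions as random, yet its regions are numbered, scored and named as peak calls. Start and end positions were deposited by the authors as other, non-signal values and are printed here counted from 1.

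The files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and tested with scipy 1.17.1. Region width was end minus start of the deposited interval. Widths were compared by a two-sided permutation test of mean log10 width with 100000 resamples. Overlap was the number of H1.4K34ac regions sharing at least 1 bp with a control region. It was set against 10000 draws in which the control regions of each chromosome were moved by 1 random circular shift. The span of a chromosome ran from position 1 to the largest end in either list, because hg18 chromosome lengths were not used here. The number of regions per chromosome was compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 24 chromosomes. The overall chromosome distribution was compared by a permutation test of the chi-square statistic with 100000 draws. Odds ratios are sample odds ratios with 95% normal-approximation intervals. Shares have 95% Wilson intervals, and densities have 95% exact Poisson intervals. All of these cover counting error only and assume independent regions, although regions of both lists cluster. Where the count was 0, the limit was set at 3 counts.

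Clustering was the share of regions with another region of the same list within 10 kb, against 10000 uniform placements per chromosome. Uniform placement also reaches sequence that the assembly leaves unresolved, which lowers the expected share at short range by an amount not measured here. The distance to the nearest region was compared between lists by relabelling regions within chromosomes in 1000 draws. Relabelled differences do not centre on 0, because the lists differ in size, so the observed difference was set against their median and both tails were counted. Score and width were compared across regions by Spearman's rho with 100000 permutations and 2000 bootstrap resamples. Regions are not independent replicates.

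Before the data were examined, 3 groups of chromosomes were fixed: gene-dense (1, 11, 16, 17, 19 and 22), gene-poor (4, 13, 18, X and Y) and those with amplicons known in MCF-7 (1, 3, 17 and 20). They were tested in the same way, adjusted over the 3 groups. The regions named in the text follow a rule fixed at the same time. It takes the 10 highest scores and the 5 widest regions of each list, every chromosome past an adjusted p of 0.05, and the 5 windows of 1 Mb with most regions per list. Tests of transcription start sites, preset gene lists and base composition had also been planned. They need the sequence or annotation of hg18, which was not used here, and were not run. For the same reason no region is assigned to a gene, exon or intron.

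Alternatives were stricter lists (the upper 50% by score), merging of regions within 1 kb, other overlap rules, other placements, other windows, covered length or 1 Mb windows as units, and leaving out chromosome Y. Counting the region numbers that have no listed region, leaving out the segments around them, and repeating the score correlation in the upper 50% by score were added after the data were seen. Each statistic was tested on simulated lists. Overlap used lists with the real widths and numbers of regions (3072 and 2209), and clustering used those of the H1.4K34ac list. Counts per chromosome were drawn independently with the real totals, so the chromosome rates below do not cover lists whose regions cluster. The neighbour distance was tested without the size difference of the real lists. Width and the score correlation were tested on simulated widths. All 50 of 50 planted overlaps were recovered. Each had been placed inside an H1.4K34ac region, so this checks the counting and not how small an excess the shift test can detect. Of chromosomes whose share was multiplied by 2, 97.2% were called, and 6.5% of 200 simulations without a difference called any chromosome. A list with 200 planted neighbours gave 4.76 times the expected share within 10 kb, and an unrelated list gave 0.895 times.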

Results

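To map where H1.4K34ac is enriched in the genome of MCF-7 cells, regions called from an immunoprecipitation with an antibody against the modification were set beside regions called from a control without antibody. Linker histones such as H1.4 bind nucleosomes where the DNA enters and leaves, and H1.4K34ac is the form acetylated at lysine 34. The H1.4K34ac list held 3072 regions covering 2.80 Mb on 23 chromosomes, the autosomes and X. The control list held 2209 regions covering 0.260 Mb on 24 chromosomes, Y included. Each list stands for 1 sample and the depth of the libraries is unknown, so all intervals below describe regions within these lists. The regions of the control list were numbered without a gap up to 2209. In the H1.4K34ac list the numbers ran to 3105, and 33 of them had no region.

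Listed H1.4K34ac regions were much wider than listed control regions. The smallest widths were 260 bp in the H1.4K34ac list and 44 bp in the control list. The calling settings and the depth are unknown, so how far the calling sets the widths cannot be told. The median width was 753.5 bp in the H1.4K34ac list, with quartiles of 598 and 1050 bp, and 91 bp in the control list, with quartiles of 60 and 119 bp. The geometric mean width was 8.57 times larger in the H1.4K34ac list (log10 difference 0.933 ± 0.00629, SE over regions; two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Of the H1.4K34ac regions, 852 (27.7%) were wider than 1 kb, against 4 (0.181%) of the control regions. The widest H1.4K34ac region spanned 4757 bp on chromosome 8 (129232311 to 129237067, hg18). The next lay on chromosome 17 (54523819 to 54528552, 4734 bp), chromosome 1 (114152290 to 114156515, 4226 bp), chromosome 20 (55054929 to 55058972, 4044 bp) and chromosome 1 again (114853441 to 114857480, 4040 bp). The regions on chromosomes 17, 1 and 20 all lay inside or within 0.420 Mb of the segments that hold the region numbers without a region. The widest control regions lay on chromosome 1 (121185650 to 121186963, 1314 bp), chromosome 6 (58886085 to 58887314, 1230 bp, and 58885030 to 58886065, 1036 bp), chromosome 17 (38755603 to 38756723, 1121 bp) and chromosome 20 (51798645 to 51799637, 993 bp).

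The highest H1.4K34ac scores belonged to regions of 1 to 5 kb on few chromosomes. The top 2 regions, with scores of 552.76 and 460.83, lay side by side on chromosome 8 (43214814 to 43216176 and 43211752 to 43213193), and a region between them (43213480 to 43214807) ranked 10 with 268.39. Both of the top 2 contained a control region, with control scores of 134.11 and 210.52. Rank 3 was on chromosome 17 (53330441 to 53332379, score 449.82), where rank 6 also lay (54523819 to 54528552, score 302.87). Chromosome 11 held rank 4 (85214759 to 85216768, score 324.55) and rank 7 (74738829 to 74741822, score 301.24). The others of the top 10 were on chromosome 12 (50828994 to 50832830, score 319.27), chromosome 16 (87515571 to 87519330, score 295.76) and chromosome 8 (123861526 to 123864659, score 287.56). Over the whole list the median score was 60.75, and 291 regions (9.47%) scored 100 or more.

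The 10 highest control scores belonged to regions of 141 to 1314 bp, which was wide for that list. The top region was on chromosome 1 (121185650 to 121186963, score 2685.55), followed by chromosome 1 (91625343 to 91625757, score 2093.14) and chromosome 7 (61606647 to 61607001, score 1717.17). The next were on chromosome 12 (20595631 to 20595771, score 1175.47), chromosome 6 (58886085 to 58887314, score 1140.52) and chromosome 11 (84872655 to 84872931, score 1032.66). The remaining members of the top 10 were on chromosome 5 (71182493 to 71182703, score 1026.04), chromosome 8 (70764844 to 70765173, score 889.24), chromosome 11 (11224654 to 11225125, score 803.45) and chromosome 1 (154452858 to 154453285, score 797.17).

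Score rose with width among H1.4K34ac regions and fell with width among control regions. Across the 3072 H1.4K34ac regions, Spearman's rho between score and width was 0.515 (95% bootstrap interval 0.487 to 0.542; permutation p = 1e-05, the smallest possible). Pearson's r of the log10 values was 0.564. Across the 2209 control regions rho was -0.32 (95% bootstrap interval -0.358 to -0.277; permutation p = 1e-05) and Pearson's r of the log10 values was -0.138. The rho of the H1.4K34ac list was higher by 0.835 (95% bootstrap interval 0.784 to 0.882). The 10% of H1.4K34ac regions with the highest scores had a median width of 1390 bp and the 10% with the lowest scores 633 bp. In the control list the corresponding medians were 81 and 112 bp. Within the upper 50% of the control list by score, rho was 0.0779, so the negative sign did not hold there. These relations are across regions, which are not independent replicates.

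**Figure D1:**
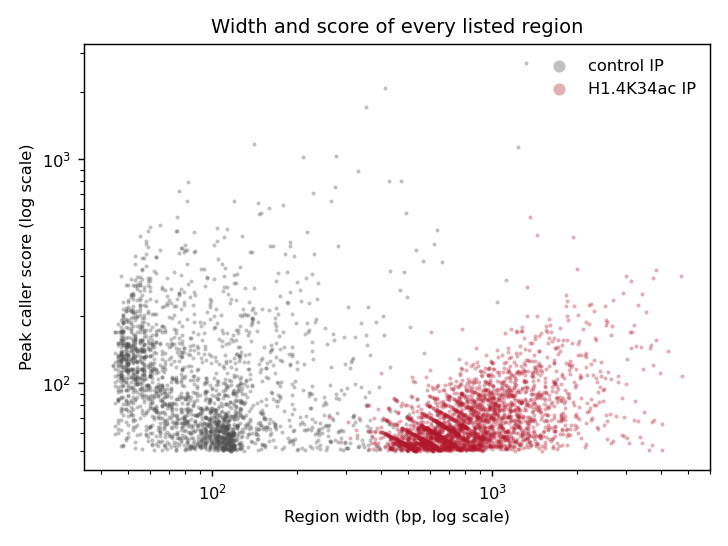
Each point is 1 listed region, with its width in bp on the x axis and the score given by the authors' peak caller on the y axis, both on log scales. H1.4K34ac regions (median 753.5 bp) form a band that rises to the right, and control regions (median 91 bp) lie to the left of it with scores up to 2685.55.

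The lists hardly met at base-pair level. Of the 3072 H1.4K34ac regions, 5 shared at least 1 bp with a control region, where circular shifts of the control list gave 2.68 on average with a 95% range of 0 to 7 (two-sided permutation p = 0.291). The excess was therefore not distinguishable from chance placement. If 1 library served as background for calling the other list, which is not known, low overlap and separate dense windows would partly follow from the calling. Besides the pair on chromosome 8, the overlapping regions were on chromosome 17 (38821208 to 38822486, score 59.51, and 55907102 to 55910117, score 57.1) and chromosome 20 (48407830 to 48411547, score 67.46). Within 1 kb of a control region lay 9 H1.4K34ac regions against 7.11 in shifted lists (permutation p = 0.593).

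The gene-poor chromosomes as a group held a smaller share of H1.4K34ac regions than of control regions. The preset gene-poor group (4, 13, 18, X and Y) held 130 of 3072 H1.4K34ac regions, or 4.23% (95% Wilson interval 3.58 to 5.00%). It held 342 of 2209 control regions, or 15.5% (14.0 to 17.1%), which gives an odds ratio of 0.241 (0.196 to 0.298; Fisher's exact test, adjusted p = 1.4e-44). Without chromosome Y the odds ratio was 0.331 (Fisher's exact test, adjusted p = 1.13e-23). With 1 Mb windows as units, so that a dense cluster counts once, it was 0.575 (Fisher's exact test, adjusted p = 0.000347). That value includes chromosome X, with 21 against 42 windows, and Y, with 0 against 7. Chromosomes 4, 13 and 18 had window ratios of 0.771, 0.745 and 0.697 (Fisher's exact test, adjusted p = 0.863 for each). The group without both X and Y was not tested. With regions as units, chromosome 13 of this group was not called by itself, with 31 H1.4K34ac and 32 control regions (odds ratio 0.694, 0.422 to 1.14; Fisher's exact test, adjusted p = 0.224). The gene-dense group (1, 11, 16, 17, 19 and 22) held 30.6% of H1.4K34ac regions and 25.2% of control regions (odds ratio 1.31, 1.16 to 1.48; Fisher's exact test, adjusted p = 2.89e-05). This difference ended when 1 Mb windows were the units (odds ratio 0.995; Fisher's exact test, adjusted p = 0.96). The chromosomes with amplicons known in MCF-7 (1, 3, 17 and 20) held 26.7% and 23.8% (odds ratio 1.16, 1.02 to 1.32; Fisher's exact test, adjusted p = 0.0194). That call was lost without chromosome Y (odds ratio 1.10; Fisher's exact test, adjusted p = 0.147) and with 1 Mb windows as units (1.11, adjusted p = 0.466), and the ratio turned to 0.838 for covered length. It was 1.48 (Fisher's exact test, adjusted p = 2.64e-08) without the segments that hold the region numbers lacking a region, and 1.26 (adjusted p = 0.00233) for the upper 50% of the H1.4K34ac list by score.

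Over all chromosomes the distributions differed (permutation test of the chi-square statistic, p = 1e-05, the smallest possible). With 1 Mb windows as units the difference did not pass (permutation p = 0.0945). Fisher's exact tests called 15 of 24 chromosomes after adjustment. Higher shares in the H1.4K34ac list were found for 8 of them. The largest odds ratio was that of chromosome 14, with 168 H1.4K34ac regions (5.47%) and 65 control regions (2.94%), an odds ratio of 1.91 (1.43 to 2.55; Fisher's exact test, adjusted p = 5.33e-05). The odds ratio was 1.67 for chromosome 15, 1.51 for chromosome 12, 1.47 for chromosome 3 and 1.44 for chromosome 1. The call of chromosome 15 was lost in the upper 50% of the H1.4K34ac list by score (odds ratio 1.52; Fisher's exact test, adjusted p = 0.103). It was 1.4 for chromosome 9, 1.37 for chromosome 11 and 1.34 for chromosome 8, and these 3 calls were lost without chromosome Y (Fisher's exact test, adjusted p = 0.0516, 0.0946 and 0.078), with odds ratios of 1.34, 1.31 and 1.28.

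Lower shares in the H1.4K34ac list were found for the other 7 called chromosomes. Chromosome Y held none of the 3072 H1.4K34ac regions, which allows a share of up to 0.0977%, and 93 control regions (4.21%; Fisher's exact test, adjusted p = 4.77e-35). Whether the cells carry a Y chromosome was not examined, so this absence cannot be read as a trait of the modification. Chromosome X held 26 H1.4K34ac regions (0.846%) and 79 control regions (3.58%), an odds ratio of 0.23 (0.147 to 0.36; Fisher's exact test, adjusted p = 3.95e-11). The odds ratio was 0.37 for chromosome 4, 0.376 for chromosome 18, 0.635 for chromosome 10, 0.638 for chromosome 20 and 0.725 for chromosome 2. On chromosome 10, 47 of the 133 control regions lay between 41 and 42 Mb, beside 0 H1.4K34ac regions. Of the 185 on chromosome 2, 35 lay between 91 and 92 Mb and 30 between 132 and 133 Mb, beside 0 and 2 H1.4K34ac regions. With 1 Mb windows as units the ratios of chromosomes 10 and 2 were 1.20 and 1.08 (Fisher's exact test, adjusted p = 0.863 for each). Chromosome 20 was lower only through the segment between 43996296 and 54634642, which held 80 of its 143 control regions and 19 of the region numbers without a region. With that segment and its counterparts on chromosomes 1 and 17 left out, its odds ratio was 1.02 (Fisher's exact test, adjusted p = 0.934), and that of chromosome 17 rose from 1.08 (adjusted p = 0.571) to a called 1.68 (adjusted p = 0.000435). With 1 Mb windows as units, only chromosome X remained called (odds ratio 0.421; Fisher's exact test, adjusted p = 0.029), no chromosome was called higher, and 2 were lower at an unadjusted p under 0.05.

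**Figure D2:**
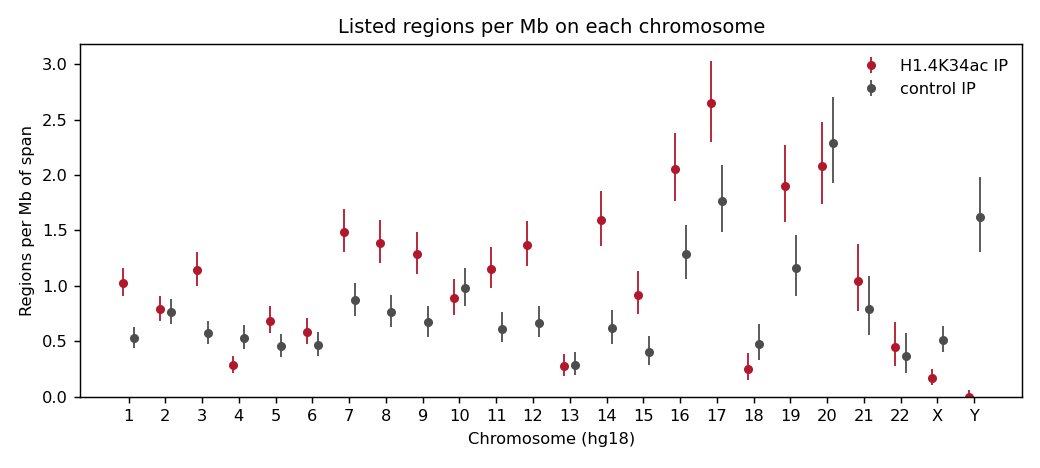
Regions per Mb of chromosome span (up to the last region of either list, hg18) on the y axis for each chromosome on the x axis, with points for the H1.4K34ac list and the control list and bars for 95% exact Poisson intervals. The H1.4K34ac density ran from 0 on chromosome Y and 0.169 on X to 2.64 on chromosome 17, and the control density was highest on chromosome 20, at 2.29.

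Regions of both lists lay in clusters. In the H1.4K34ac list 809 regions (26.3%) had another region of the list within 10 kb, 9.27 times the 2.84% expected from uniform placement (two-sided permutation p = 0.0002, the smallest that 10000 draws can give). In the control list 805 regions (36.4%) had one, against an expected 1.82% (permutation p = 0.0002). The ratio shrank with distance, to 2.35 and 3.15 times at 100 kb and 1.04 times in both lists at 1 Mb. At 100 kb the shares were 53.9% against an expected 22.9% (H1.4K34ac) and 51.1% against 16.2% (control). At 1 Mb 87.9% and 77.2% were expected, so the ratio had little room to rise and does not show that clustering is only short-range. Merging regions within 1 kb left 6.40 times in the H1.4K34ac list. The median distance to the nearest region of the same list was 76.8 kb in the H1.4K34ac list and 84.3 kb in the control list. The ratio of these medians, H1.4K34ac over control, was 1.34 times that of relabelled lists (log10 difference 0.127 above the relabelled median, permutation p = 0.002). Without the segments that hold the region numbers lacking a region it was 1.14 times (log10 difference 0.0571, permutation p = 0.128), so the call was lost. With regions within 1 kb merged the ratio was 0.76 times that of relabelled lists (permutation p = 0.002), so the direction of the departure from relabelled lists turned, while the H1.4K34ac median stayed the smaller of the 2 (104 against 219 kb).

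**Figure D3:**
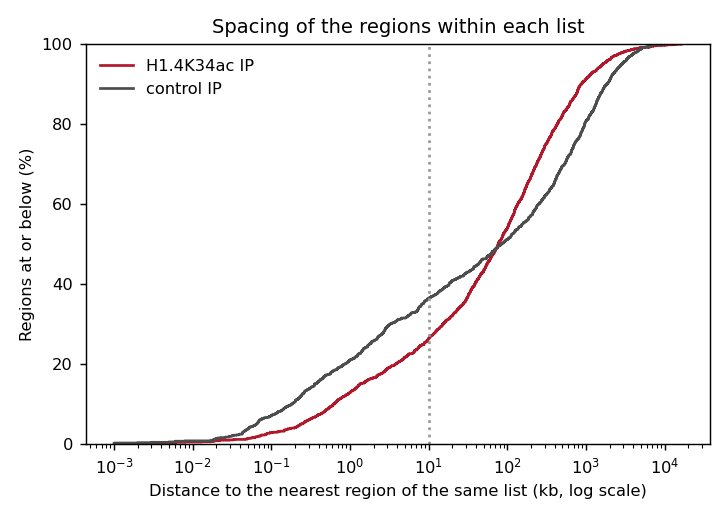
Cumulative percentage of regions (y axis) whose nearest region of the same list lies at or below the distance on the x axis (kb, log scale), with 1 line per list and a dotted line at 10 kb. At 10 kb the control line stands at 36.4% and the H1.4K34ac line at 26.3%, and the lines cross near the medians of 84.3 and 76.8 kb.

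The densest parts of the lists lay in different places. The 1 Mb window with most H1.4K34ac regions was 71 to 72 Mb on chromosome 17, with 23 regions covering 28.6 kb and no control region. The next was 58 to 59 Mb on chromosome 17, with 21 H1.4K34ac and 7 control regions. It was followed by 84 to 85 Mb on chromosome 16 and 131 to 132 Mb on chromosome 9, with 18 each and with 2 and 1 control regions. Rank 5 was 51 to 52 Mb on chromosome 12, with 17, beside 1 control region. A further window with 17 lay at 61 to 62 Mb on chromosome 20, beside 5 control regions. The densest control windows were 41 to 42 Mb on chromosome 10 with 47 regions, 91 to 92 Mb on chromosome 2 with 35 and 12 to 13 Mb on chromosome Y with 34. The windows at 44 to 45 Mb on chromosome 16 and at 61 to 62 Mb on chromosome 7 held 33 and 32 control regions. None of these 5 control windows held an H1.4K34ac region. Windows with 10 or more regions numbered 35 in the H1.4K34ac list and 33 in the control list, and no window was in both sets. They held 15.4% of the H1.4K34ac regions and 29.5% of the control regions. No expected number of shared windows was computed, so the lack of shared windows is a description only.

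On chromosomes 17 and 20 control regions were concentrated where region numbers of the H1.4K34ac list had no region. Between 54190285 and 58155465 on chromosome 17 lay 58 control regions, or 14.6 per Mb against 1.08 per Mb elsewhere on that chromosome. In the same segment 15 H1.4K34ac regions were listed, or 3.78 per Mb against 2.58 per Mb elsewhere on that chromosome, and 12 numbers had no region. In the chromosome 20 segment control regions stood at 7.52 per Mb against 1.22 elsewhere, beside 36 listed H1.4K34ac regions, at 3.38 per Mb against 1.82 elsewhere. A further segment, on chromosome 1 (114249105 to 115012867), held 2 control regions, 2 H1.4K34ac regions and 2 numbers without a region.

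**Figure D4:**
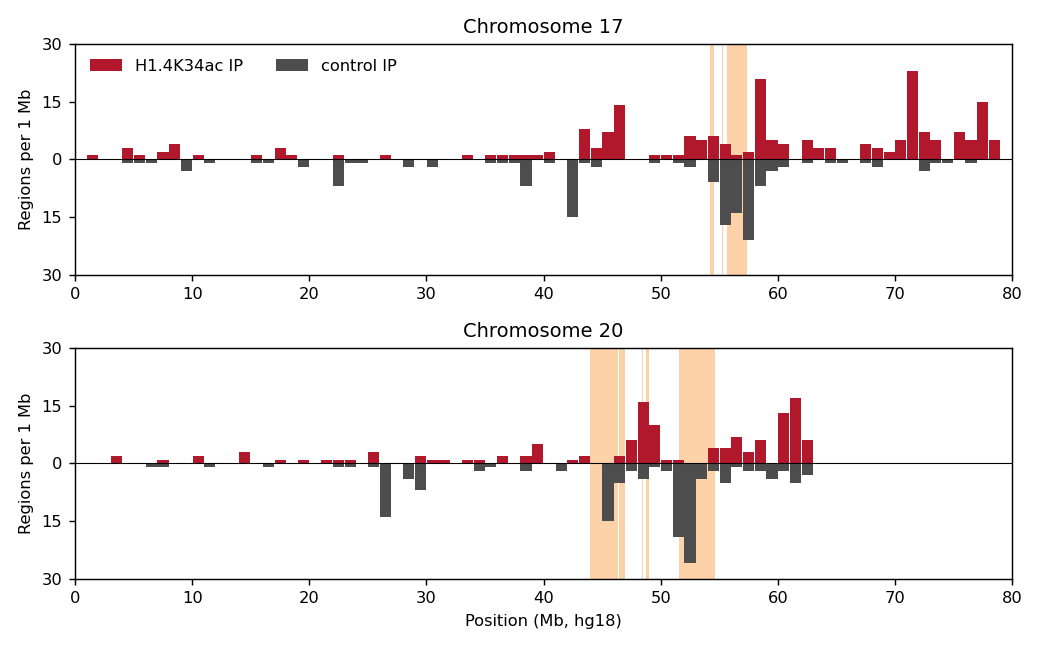
Regions per 1 Mb window along chromosomes 17 and 20 (x axis, position in Mb, hg18), with H1.4K34ac regions drawn upward and control regions downward from 0 and shading over the intervals between listed neighbours that hold region numbers without a region. Over the segments that span the shaded intervals, control regions stand at 14.6 per Mb on chromosome 17 and 7.52 per Mb on chromosome 20, and 2 of the shaded intervals hold 0 control regions.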

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

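The tests in this part were chosen after the numbering had been seen. The name column, which no comparison used, showed that 33 region numbers of the H1.4K34ac list have no region, while the control list has no such gap. Numbers follow position along each chromosome, so each gap can be placed between listed neighbours. They fell into 13 stretches on 3 chromosomes, 2 numbers on chromosome 1, 12 on chromosome 17 and 19 on chromosome 20. At which step they left the list used here is not known.

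Loss at random along the list is excluded, since 10000 random draws of 33 regions covered 15.8 chromosomes on average and never fewer than 10, against 3 observed. Removal because each overlapped a control region is excluded as the whole cause, since 3 of the numbers had no control region between their listed neighbours and 5 regions that do overlap one are listed. That the numbers mark segments amplified in MCF-7 stays open as a hypothesis formed from the values that follow, which go with it but give no independent support: the 3 segments, 1 per chromosome, all lay on chromosomes preset for an amplicon, with 26.7% of the gaps between neighbours (hypergeometric exact p = 0.019), and held 140 control regions, 4.43 times the mean of circular shifts (permutation p = 0.0003). The H1.4K34ac regions still listed there were 2.12 times wider than those elsewhere (95% interval 1.85 to 2.43; permutation p = 1e-05). Neighbouring regions of 3 segments are not independent, so this interval and p-value describe the listed regions only. The greater width goes with raised copy number, but no copy number was measured and stronger enrichment in these segments stays open. No biological explanation was tested.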

How the results depend on the processing

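Of 36 alternative values with a p for 10 tested comparisons, 30 kept direction and side of the threshold, as did 51 of 74 for the 15 called chromosomes. Alternatives without the segments around the numbers lacking a region, with those numbers counted, and within the upper 50% of each list by score for rho, were chosen after seeing the data. With 1 Mb windows as units, 0 chromosomes were called higher (0 also at an unadjusted p under 0.05 by Fisher's exact test) and 1 lower, the gene-dense odds ratio was 0.995 and the amplicon odds ratio 1.11. The ratios of chromosomes 2 (1.08), 8 (0.896), 9 (0.873), 10 (1.20) and 11 (0.743) then changed direction, and 9 other chromosome calls were lost. Windows count a dense cluster once, by construction. In the upper 50% of the H1.4K34ac list by score, chromosomes 15 (1.52) and 20 (0.794) lost their calls. Without chromosome Y, 5 chromosomes were called higher and the amplicon odds ratio was 1.10. It was 0.838 for covered length, and the cause was not tested. Without the segments, the calls of chromosomes 8 (1.27), 9 (1.33) and 11 (1.30) were lost with little change of the ratio, that of chromosome 20 was lost with its ratio (1.02), chromosome 17 was called higher (1.68), the amplicon odds ratio was 1.48 and the log10 neighbour distance above the relabelled median 0.0571 (permutation p = 0.128, against 0.002 in the alternative with merging). That distance was -0.119 with regions within 1 kb merged. Rho of the control list was 0.0779 in its upper 50% by score, and the cause was not tested. Merging touching regions altered nothing, since none touch. Clustering ratios fell to 1.04 at 1 Mb in both lists, where expected shares of 87.9% and 77.2% left them little room. The overlap ratio ranged from 1.27 to 2.09 and never passed (p from 0.21 to 0.688). Alternatives for start sites, gene lists and base composition were not run, as hg18 annotation was not used here. No paired analysis was possible because each group has 1 list. Depth is unknown, so weak or missing regions cannot be told from low coverage.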

Other observations

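Among the tests in this part, those of regions inside and outside the segments around the absent region numbers, of overlapping regions among the highest scores, of both lists beside the longest stretches and of control regions on both sides of a stretch were chosen after the data were seen. Control regions inside these 3 segments differed in kind from the rest. The 140 inside had a median width of 283 bp and a median score of 59.6, and the 2069 outside had 86 bp and 90.85. Inside they were 2.95 times wider (95% interval 2.65 to 3.30; permutation p = 1e-05), yet 1.43% of them were in the top 10% of the list by score, against 10.5% outside (odds ratio 0.123, 0.0303 to 0.50; Fisher's exact test, p = 6.11e-05). Of the 53 listed H1.4K34ac regions inside the segments, with a median width of 1654 bp against 745 bp outside, 20.8% were in the top 10% by score, against 9.80% outside (odds ratio 2.41, 1.23 to 4.73; Fisher's exact test, p = 0.0172). Nearly all regions inside lay on chromosomes 17 and 20 (58 and 80 control regions, 15 and 36 H1.4K34ac regions). Neighbouring regions are not independent, so these intervals and p-values do not measure a difference between segments.

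At a broader scale the lists lay nearer each other than shifted lists. Outside the segments, 389 of 3019 H1.4K34ac regions (12.9%) had a control region within 100 kb, 1.35 times the 9.54% of circular shifts (permutation p = 0.001, the smallest that 2000 draws can give). Within 1 Mb it was 69.8% against 56.9% (permutation p = 0.001), and within 10 kb 1.62% against 1.17% (permutation p = 0.089). Shifts also move control regions into unassembled sequence, which may lower these expected values. Of the top 10% of H1.4K34ac regions by score, 30.3% lay on chromosomes 1, 3, 17 and 20, against 26.3% of the rest (odds ratio 1.22, 0.943 to 1.58; Fisher's exact test, p = 0.135), an interval that allows no effect as well as a higher share.

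The 3 adjacent H1.4K34ac regions on chromosome 8 with ranks 1, 2 and 10 by score are separated by 286 and 6 bp. A candidate explanation is enrichment present without antibody, since 2 of the 3 highest regions overlap a control region, but these are 1 locus that prompted the idea, and of the other 3 overlapping regions 0 were in the top 10% by score. This cannot be told apart from sequence beside an unassembled stretch. The planned measure put the regions 63.5% of the chromosome span away from its longest stretch without regions (135914777 to 140290500). By the planned rule that distance would count against such sequence, but the rule presumes that the longest stretch is the unassembled one. The longest stretch has 0 and 1 control regions within 250 kb of its ends. Another (43957891 to 46960827), 0.742 Mb from the regions, has 11 and 10, but it was chosen for them after the data were seen. Whether either stretch is unassembled was not examined, so neither decides the question. No biological explanation was tested.

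For the densest windows of the control list, amplified segments as the whole cause are excluded, as far as the segments around the absent numbers represent them, since these held 17.2% of the 651 control regions in windows with 10 or more. Sequence beside unassembled stretches stays open. Control regions within 2 Mb of the longest stretch without regions on each chromosome were 1.42 times the median of shifted lists (227 against 160, permutation p = 0.0869). These 227 were 10.3% of control regions, against 2.28% of H1.4K34ac regions at the same stretches (odds ratio 4.91, 3.73 to 6.46; Fisher's exact test, p = 1.35e-35). This goes with the explanation, but regions cluster, and 70 of the 227 lay on chromosome 16. The densest control windows of chromosomes 10, 2, 7 and Y lay more than 2 Mb from the longest stretch there, so the measure missed them. Within 2 Mb of that stretch lay 1 of 133 control regions on chromosome 10 and 2 of 185 on chromosome 2. On chromosomes 7 and Y it was 3 of 138 and 15 of 93. For those windows the measure decides nothing. Whether these stretches are unassembled was not examined. Of 380 stretches of 2 Mb or more without regions, 6 had at least 5 control regions within 250 kb on each side, on chromosomes 5, 8, 10, 16, X and Y, and these flanks held 189 control regions (8.56%). These stretches were chosen for their control regions, so that share gives no support to the explanation. No biological explanation was tested.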
